A study of Homo sapiens with 6 samples.

How the data were processed

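IMR-32 cells, an established human neuroblastoma line, received DMSO or 25 nM PTC-028 for 24 h, and poly(A)-selected RNA from 3 libraries per group was sequenced. The authors deposited 1 table of TPM, a length-normalised relative transcript abundance, per gene, and these TPM values were used as deposited. TPM divides each gene's signal by its length and scales each library to a fixed total, so the values are relative to all other genes of the library. The 6 columns summed to between 999990 and 999999. The genome build was GRCh38, per the submitters' processing notes. The aligner, the quantifier and the annotation are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no interval that rests on read counts is given. Whether the replicates came from separate cultures is not stated in the labels, so the p-values measure only the spread between these libraries, which may be technical.

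The table had 23555 gene rows, of which 22507 carried an Ensembl identifier found on the primary assembly of GENCODE 29 and 21664 also carried the same version. Names and coordinates were taken from GENCODE 29 by identifier, because 83 symbols in the table had been turned into dates or decimals by a spreadsheet. The other 1048 rows, mostly copies of genes on alternative haplotypes, kept the symbol of the table and have no coordinates here. Reads of a gene with such copies can be divided between its rows, and 1189 rows shared a symbol with another row. For a gene list, the row with the highest mean TPM over all libraries stood for a symbol. The rows comprised 17490 protein-coding genes, 4982 pseudogenes and 14 long non-coding RNA genes, so long non-coding RNA was largely not analysed here.

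Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested, which left 13836. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with treatment as the only term, eBayes with a mean-variance trend, 2-sided p-values and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Errors after a log2 fold change are standard errors, and errors after a TPM are standard deviations over 3 libraries.

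In all, 34 gene lists were written before the data were examined, together with the design, the rule for named genes and most of the alternatives. They covered p53 targets, DNA replication, mitosis, tubulins and other tubulin genes, Polycomb complexes 1 and 2, reported BMI1 targets, HOX genes, MYC and ribosome biogenesis, ribosomal proteins, neuroblastoma cell states, neuronal genes, apoptosis, stress and signalling responses, DNA repair, histones, metabolism, proteasome, lysosome, housekeeping genes and markers of other cell types. The 30 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 30 lists. The same lists were tested with camera at an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its members move, on balance, one way. Counts of list members that passed are given with adjustment over all genes and, where stated, adjusted over the list alone.

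Genes are named by a fixed rule. It takes a set chosen in advance (BMI1, RNF2, RING1, EZH2, MYCN, MDM2, CDKN1A, BBC3, BAX and CDKN2A). It adds the 10 largest rises and the 10 largest falls among genes that passed, had a mean TPM of at least 5 in the higher group and showed no overlap between the groups. From each list it takes up to 4 passing members with the smallest p, or, where fewer than 2 passed, the 2 members with the smallest p. Of the genes the rule takes, 2 are not reported here. Any other gene is said to have been chosen after its values were seen.

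The procedure was tested on simulated libraries built from the means and standard deviations of the 13836 genes, with 200 genes changed in each of 10 simulations. It recovered 43.6% of genes changed 1.5-fold, 71.8% of those changed 2-fold, 81.8% of those changed 3-fold and 91.0% of those changed 4-fold, and a mean of 4.65% of its calls were false. In simulated libraries with independent genes, camera at the preset correlation found 100% of 100 lists of 40 genes shifted by 0.5 on the log2 scale, and 2% of 100 unshifted lists had p under 0.05. This does not measure its error where the genes of a list are correlated.

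The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum TPM of 5, median ratio scaling, quantile normalisation, removal of mitochondrially encoded genes, eBayes without a trend or with robust settings, limma's library weights, the replicate number as a block and the removal of each library in turn. Summing the rows of 1 symbol and a correction of each library for GC content and length were added after seeing the data. Principal components and correlations between libraries were computed on log2(TPM + 1) of the tested genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.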

Results

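Gene expression was measured by RNA sequencing in IMR-32 cells, a human neuroblastoma line with amplified MYCN, after 24 h with PTC-028 or with its solvent DMSO. PTC-028 is a compound used to inhibit BMI1, a core protein of Polycomb repressive complex 1. It was used at 25 nM, and each group had 3 libraries. The libraries held between 13580 and 14003 genes with a TPM of at least 1. Mitochondrially encoded genes took 5.60%, 4.98% and 4.50% of the TPM in the DMSO libraries and 5.39%, 5.67% and 6.00% in the PTC-028 libraries, so the groups overlapped. Across the tested genes, Pearson correlations were between 0.983 and 0.988 within groups and between 0.981 and 0.985 between groups. The first principal component held 31.2% of the variance and had all DMSO libraries on one side (-13.5, -3.62 and -24.7) and all PTC-028 libraries on the other (13.0, 15.7 and 13.1).

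The comparison of PTC-028 with DMSO addressed which genes change when BMI1 is targeted by the compound, with the p53 pathway named in the series title. In the PTC-028 libraries, targets of the transcription factor p53 were higher and genes of DNA replication were lower, while the mRNA of BMI1 itself did not pass the test. Both list calls were made by camera at a preset correlation and missed the threshold with an estimated correlation (adjusted p = 0.0528 for each), at which 0 of 30 lists passed. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 78.6 ± 1.33 to 294 ± 19.1 TPM (SD, n = 3 each), the smallest p-value of any gene tested. FEN1, a nuclease that processes Okazaki fragments, fell from 153 ± 5.11 to 93.9 ± 1.69 TPM (SD, n = 3 each). Of 13836 genes tested with limma, 260 passed, 120 higher and 140 lower in PTC-028. Genes that rose did so by a median of 1.63-fold, and genes that fell reached a median of 0.726 of their DMSO level. The fold change was at least 2 for 30 genes that rose and 5 that fell. The p53 list held 34 of the 120 genes that rose, and the replication list 36 of the 140 that fell. None of the 260 genes overlapped between the groups, and 24.0% of all genes tested showed no overlap, against 10% by chance. The number of genes that passed depended on single libraries, falling to 76 without DMSO replicate 1, 89 without PTC-028 replicate 1, 74 without PTC-028 replicate 2 and 99 without PTC-028 replicate 3. It was 226 without DMSO replicate 3, the library farthest from the others on the first component.

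**Figure D1:**
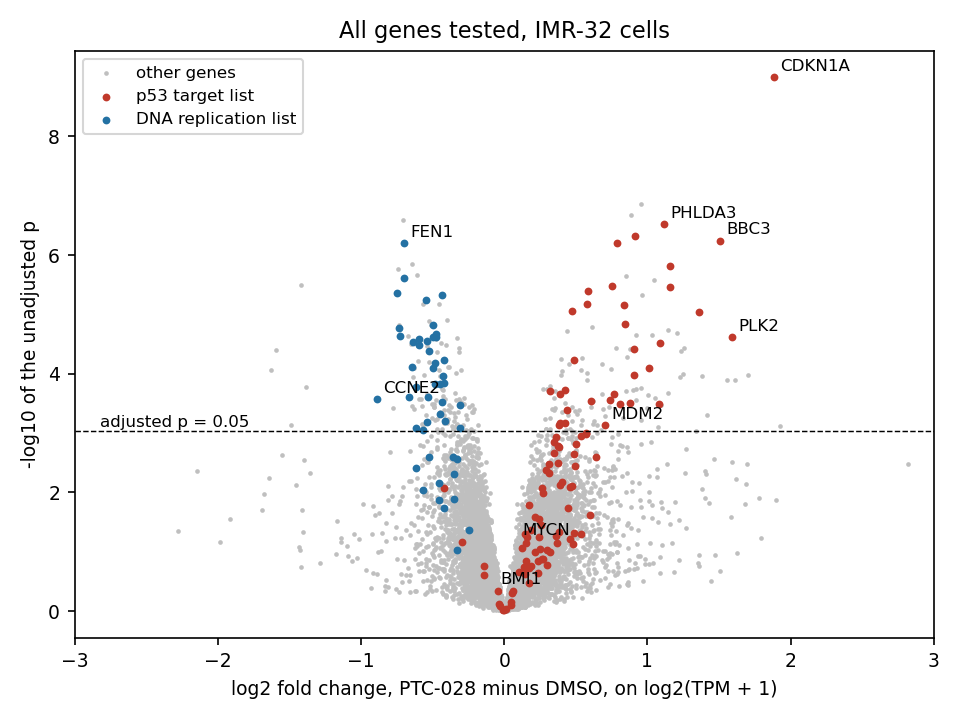
Each point is 1 of the 13836 genes tested, with the log2 fold change of PTC-028 against DMSO on the x axis (log2(TPM + 1) scale, 3 libraries per group) and -log10 of the unadjusted limma p on the y axis. Members of the p53 target list (red) lie mostly to the right and members of the DNA replication list (blue) all lie to the left of 0, and the dashed line marks the largest p that passed.

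BMI1 (chromosome 10, 22321211 to 22331484, GRCh38) had 47.9 ± 3.97 TPM in DMSO and 45.5 ± 3.55 TPM in PTC-028, a log2 fold change of -0.07 ± 0.09 (SE, n = 3 each; limma adjusted p = 0.716). The 95% confidence interval of that change ran from -0.27 to 0.13. The change was between -0.13 and -0.01 with any 1 library left out. Whether the compound inhibited the BMI1 protein cannot be read from the BMI1 mRNA level. The partners of BMI1 in the ubiquitin ligase had log2 fold changes of -0.03 for RNF2 (limma adjusted p = 0.918) and -0.16 for RING1 (0.257), the latter read from an alternative-haplotype row. RNF2 turned to 0.08 without DMSO replicate 2 and to 0.003 without PTC-028 replicate 2. None of the 22 tested genes of the Polycomb complex 1 list passed in limma, with 6 at an unadjusted p under 0.05. PCGF3 was higher and PCGF6 lower when adjusted over the list alone. PCGF6 at -0.32 (limma adjusted p = 0.0899) and PCGF3 at 0.25 (0.109) had the smallest p. Among 11 genes of Polycomb complex 2, which methylates histone H3 at lysine 27, RBBP7, a histone-binding subunit, fell by 0.31 ± 0.05 (SE; limma adjusted p = 0.0257), a call lost without DMSO replicate 1 or any 1 PTC-028 library, where its adjusted p reached 0.110. EED was at -0.42 (limma adjusted p = 0.0662) and the methyltransferase gene EZH2 at -0.22 (0.119). That list was lower by camera (adjusted p = 0.0169), but not with an estimated correlation (adjusted p = 0.265), nor by fry (0.0990), nor after quantile normalisation (0.0550), nor without DMSO replicate 2 (0.0616) or PTC-028 replicate 1 (0.0537). Of its genes 3 were lower when adjusted over the list alone.

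Genes that Polycomb complexes are known to silence were examined only as CDKN2A, the HOX list and 4 reported BMI1 targets. None of these gave a call over all genes tested, and no broader list of silenced genes was tested. CDKN2A, the locus of p16 and p14ARF, was at 0.417 ± 0.187 TPM in DMSO and 0.520 ± 0.211 TPM in PTC-028 (SD, n = 3 each), below the filter for testing. Of 24 HOX genes with values, only 9 reached the filter, and the others were not tested. None of the 9 passed in limma. At an unadjusted p under 0.05 were 2, HOXD8 at -0.25 and HOXC4 at 0.28 (limma adjusted p = 0.222 and 0.223). Of 4 genes reported as BMI1 targets, 2 were expressed enough to test and neither passed, CADM1 at 0.32 and KIF1B at 0.13 (limma adjusted p = 0.212 and 0.611). CADM1 was higher when adjusted over its list alone, and 0 HOX genes passed that way. KIF1B turned to -0.02 after correction for GC content and length.

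MYCN (chromosome 2, 15940564 to 15947007) had 1089.6 ± 27.0 TPM in DMSO and 1154 ± 34.1 TPM in PTC-028, and its log2 fold change of 0.08 ± 0.04 did not pass (SE; limma adjusted p = 0.321). In the list of MYC targets and ribosome biogenesis genes, 1 of 50 passed, and the same number adjusted over the list alone. This was CDK4, a kinase of the G1 phase, which fell by 0.22 (limma adjusted p = 0.0282) but lost the call without any single library other than DMSO replicate 3 (adjusted p up to 0.129) and under median ratio scaling or quantile normalisation. NOP56 in that list was at -0.17 (limma adjusted p = 0.126). None of 77 ribosomal protein genes passed in limma, with 5 at an unadjusted p under 0.05, and RPL12 and RPL38, those with the smallest p, were at 0.09 and 0.10. None passed when adjusted over the list alone. That list did not pass by camera with all libraries (adjusted p = 0.903), but was lower without DMSO replicate 2 (adjusted p = 0.00454) and higher without DMSO replicate 3 (adjusted p = 0.00564).

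Of 106 tested targets of p53, 34 rose, none fell and 72 did not pass. Adjusted over the list alone, 61 were higher and 1, NINJ1, was lower, a gene named after its value was seen. The list had a median log2 fold change of 0.38, with 97 members above 0, and was higher by camera (adjusted p = 3.18e-30) and by fry (adjusted p = 0.00235). With an estimated correlation the list missed the threshold (adjusted p = 0.0528). Without DMSO replicate 1 or any 1 PTC-028 library, between 16 and 19 members passed.

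CDKN1A (chromosome 6, 36676460 to 36687339) rose by 1.89 ± 0.06 on the log2 scale (SE, n = 3 each; limma adjusted p = 1.398e-05). BBC3, which encodes the pro-apoptotic protein PUMA (chromosome 19, 47220822 to 47232766), rose from 9.59 ± 0.224 to 29.2 ± 3.57 TPM (SD, n = 3 each; limma adjusted p = 0.000961). Expression of TNFRSF10B, a death receptor for TRAIL, rose from 65.7 ± 4.47 to 125 ± 2.16 TPM, and that of PHLDA3, an inhibitor of AKT signalling, from 30.1 ± 2.26 to 66.2 ± 0.608 TPM. The kinase gene PLK2 and the receptor gene EDA2R rose by 1.59 ± 0.18 and 1.36 ± 0.13 on the log2 scale (SE). Each of these 6 genes passed in all alternatives, with every library left out in turn. MDM2, which encodes the ubiquitin ligase that degrades p53 (chromosome 12, 68808176 to 68850686), rose from 74.2 ± 14.4 to 120.5 ± 9.71 TPM (limma adjusted p = 0.0432). That call was lost without DMSO replicate 1 or any 1 PTC-028 library, with an adjusted p of up to 0.141. BAX was at 229 ± 33.6 TPM in DMSO and 331 ± 31.6 TPM in PTC-028 and missed the threshold (limma adjusted p = 0.0548). In the list of BCL2 family and caspase genes, which shares 4 members with the p53 list, BBC3 was the 1 member of 26 that passed, and the list as a whole did not (camera adjusted p = 0.850). Of the 26, 2 were higher when adjusted over the list alone.

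Of 48 tested genes of DNA replication and the G1/S transition, 36 fell and 12 did not pass. All 48 had a log2 fold change below 0, between -0.89 and -0.24 with a median of -0.50. Adjusted over the list alone, 47 were lower. The list was lower by camera (adjusted p = 1.97e-52) and by fry (adjusted p = 0.00235). With an estimated correlation its adjusted p was 0.0528. Without DMSO replicate 1 or any 1 PTC-028 library, between 16 and 22 members passed. FEN1 (chromosome 11, 61792637 to 61797244) fell by 0.70 ± 0.05 on the log2 scale (SE, n = 3 each; limma adjusted p = 0.000961). CDC45 and MCM4, parts of the replicative helicase, fell from 71.2 ± 1.97 to 42.0 ± 2.95 TPM and from 257 ± 16.6 to 156 ± 15.4 TPM (SD, n = 3 each). TK1 and TYMS, enzymes of thymidine nucleotide synthesis, fell from 177 ± 4.78 to 109 ± 6.65 TPM and from 369 ± 9.33 to 273 ± 2.44 TPM. The chromatin assembly gene CHAF1B fell by 0.73 ± 0.08 (SE). Calls for these 6 genes were kept in all alternatives. CCNE2, which encodes cyclin E2, had the largest fall of the list, from 20.6 ± 2.95 to 10.7 ± 1.74 TPM (limma adjusted p = 0.0258). It did not pass without DMSO replicate 1 or 2 or PTC-028 replicate 1 or 2 (adjusted p up to 0.105).

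**Figure D2:**
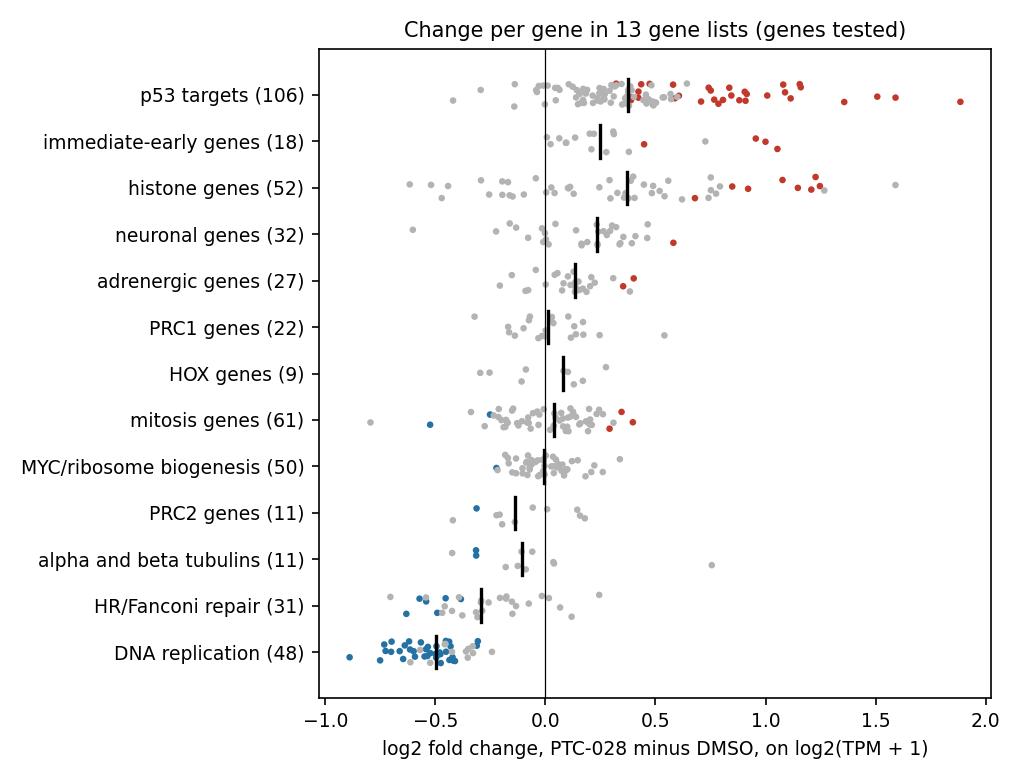
Log2 fold change of PTC-028 against DMSO on the log2(TPM + 1) scale (x axis) for each tested gene of 13 of the lists (rows, with the number of genes tested), 3 libraries per group. Red and blue points passed in limma, higher or lower, grey points did not, and black bars mark medians, which ran from -0.50 for DNA replication to 0.38 for p53 targets.

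Of 61 tested genes of G2 and mitosis, 3 rose and 2 fell, and the list did not pass (camera adjusted p = 0.759). With adjustment over the list alone, 4 were higher and 6 lower. Its median log2 fold change was 0.04 and its mean 0.003, whereas camera, which compares with all genes and their median of 0.03, pointed downwards. The mitotic kinase gene PLK1 rose from 90.4 ± 2.57 to 119 ± 3.62 TPM (SD, n = 3 each; limma adjusted p = 0.0106), the kinesin gene KIF20A rose by 0.35 and CDC20, an activator of the anaphase-promoting complex, rose by 0.29 on the log2 scale. CDK1, the kinase that drives entry into mitosis, fell from 122 ± 3.78 to 84.8 ± 6.94 TPM (limma adjusted p = 0.0112). CDK1 lost its call without PTC-028 replicate 3 (adjusted p = 0.0504), and PLK1 without DMSO replicate 1 or PTC-028 replicate 2 or 3 (up to 0.0667). KIF20A lost it without DMSO replicate 1 or any 1 PTC-028 library (adjusted p up to 0.117), and CDC20 without any 1 library (up to 0.175), under median ratio scaling and with a pseudocount of 0.1.

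Homologous recombination and Fanconi anaemia genes were lower as a list, with 6 of 31 members lower and none higher, a median of -0.29 and a camera adjusted p of 2.92e-12. With an estimated correlation the adjusted p was 0.150. Adjusted over the list alone, 15 were lower. The nuclease gene EXO1 fell by 0.63 ± 0.08 and BRCA1 by 0.45 ± 0.06 on the log2 scale (SE; limma adjusted p = 0.0127 and 0.0130). RBBP8, which starts resection of DNA ends, fell by 0.54 and FANCL, a ubiquitin ligase of the Fanconi pathway, by 0.38. EXO1 lost its call without DMSO replicate 1 or PTC-028 replicate 1 or 2 (adjusted p up to 0.0689), and BRCA1 without DMSO replicate 1 or PTC-028 replicate 2 or 3 (up to 0.0673). RBBP8 lost it without DMSO replicate 1 or any 1 PTC-028 library (adjusted p up to 0.106), and FANCL without any library other than DMSO replicate 3 (up to 0.134).

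**Figure D3:**
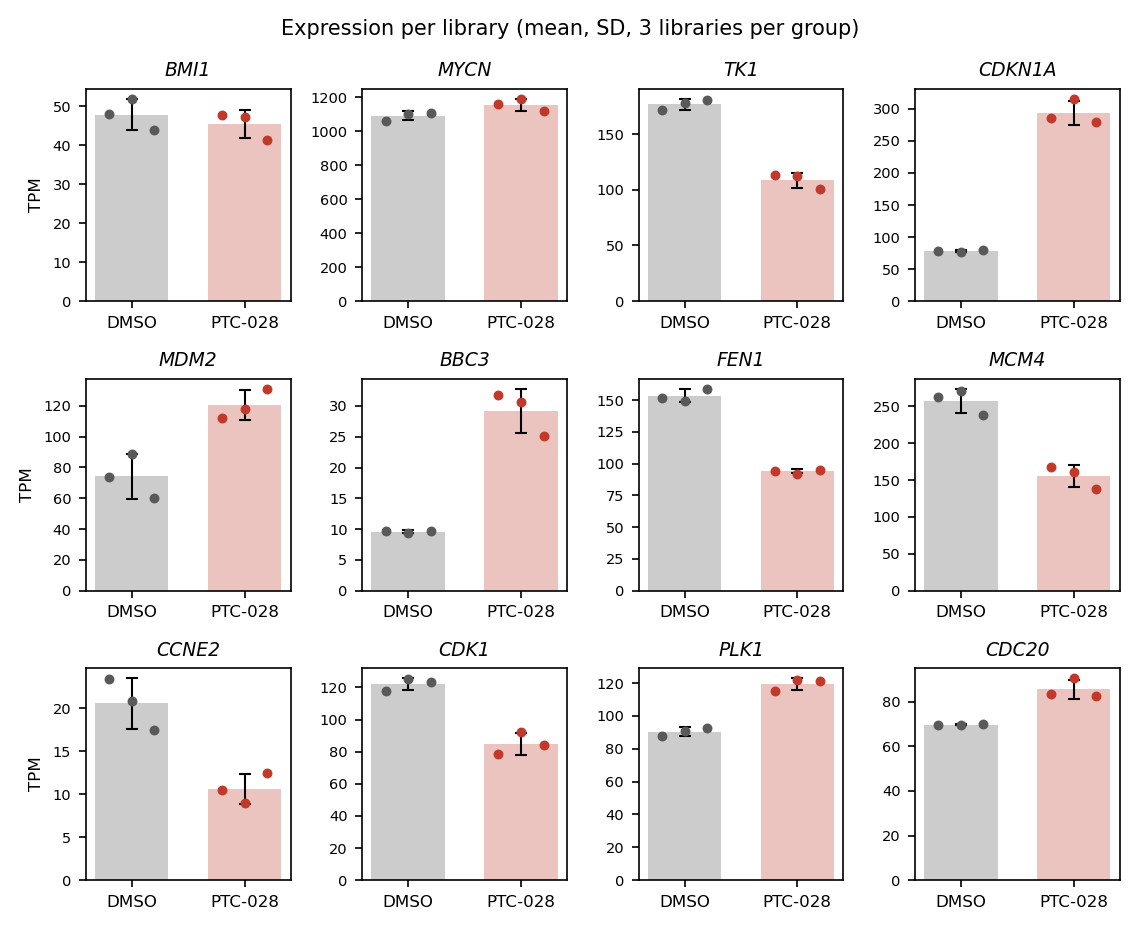
TPM of 12 genes in each library (points), with the mean (bar) and standard deviation (line) of 3 libraries per group, on y axes that start at 0. For CDKN1A the PTC-028 mean was 294 TPM against 78.6 TPM in DMSO, FEN1 lay at 93.9 against 153 TPM, and the values for BMI1 overlapped between the groups.

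Of 52 tested genes of replication-dependent histones, 8 rose, none fell and 44 did not pass, with a median of 0.37 and 39 members above 0 (camera adjusted p = 3.68e-05, adjusted p = 0.0528 with an estimated correlation). Adjusted over the list alone, 15 were higher and 1 was lower. HIST1H2BK rose from 43.7 ± 0.519 to 79.7 ± 6.49 TPM (SD, n = 3 each; limma adjusted p = 0.00222), HIST1H2AC from 2.54 ± 0.232 to 6.84 ± 0.553 TPM and HIST2H2BE from 2.37 ± 0.404 to 6.76 ± 0.286 TPM, and these 3 calls were kept in all alternatives. HIST1H2BD and HIST1H2BJ rose by 1.25 and 1.23 on the log2 scale, calls that were lost without DMSO replicate 1 or PTC-028 replicate 1 or 2 (adjusted p up to 0.0752 and 0.0772). Histone genes share near-identical sequence, so the split of reads between them is uncertain. The RNA was poly(A)-selected, so histone RNA without a poly(A) tail was measured only where it was carried over. These values therefore do not give the total amount of histone RNA.

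Immediate-early genes, which respond within minutes to growth factor and stress signals, were higher as a list. All 18 tested members had a log2 fold change above 0 with a median of 0.25, and 4 rose (camera adjusted p = 9.48e-06, adjusted p = 0.0528 with an estimated correlation). Within the list alone, 5 passed as higher. The 4 were the transcription factor genes EGR1, from 2.24 ± 0.346 to 5.78 ± 1.14 TPM, and JUN, from 18.8 ± 0.853 to 26.0 ± 1.58 TPM, the phosphatase gene DUSP6, from 2.07 ± 0.550 to 5.10 ± 0.552 TPM, and the synaptic gene ARC, from 6.35 ± 1.78 to 13.0 ± 1.39 TPM (SD, n = 3 each). Their limma adjusted p lay between 0.0252 for EGR1 and 0.0387 for ARC. EGR1 and ARC kept the call without DMSO replicate 2, EGR1 also without PTC-028 replicate 1 and JUN without DMSO replicate 3. Every other removal of 1 library ended these calls, with adjusted p up to 0.104 for EGR1, 0.149 for ARC, 0.147 for JUN and 0.127 for DUSP6, and JUN also lost its call after quantile normalisation.

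In the list of alpha and beta tubulins, the subunits of microtubules, 2 of 11 tested genes fell, and 2 were lower adjusted over the list alone. TUBA1B (chromosome 12, 49127782 to 49131397) fell from 2207 ± 74.2 to 1775 ± 45.4 TPM (SD, n = 3 each; limma adjusted p = 0.00823). TUBB fell by 0.31 ± 0.04 on the log2 scale in the most abundant of its 3 rows, all of alternative haplotypes (SE; limma adjusted p = 0.00786), and the sum of the 3 went from 1622 ± 20.9 to 1316.5 ± 44.4 TPM. Both calls were lost without PTC-028 replicate 2 (adjusted p = 0.0538 for TUBA1B and 0.0530 for TUBB). The list had a median of -0.11 and was lower by camera (adjusted p = 0.00182), but neither with an estimated correlation (adjusted p = 0.313), nor by fry (0.0615), nor after quantile normalisation (0.0668). Among 15 other tubulin genes and tubulin chaperones, TUBG1, which encodes gamma-tubulin, fell by 0.30 (limma adjusted p = 0.0277), a call lost without any library other than DMSO replicate 3 (adjusted p up to 0.130). It was also the 1 gene lower adjusted over the list alone. TBCA was at -0.14 (limma adjusted p = 0.218). That list did not pass (camera adjusted p = 0.625), with a median of 0.04, a mean of -0.001 and a test that pointed downwards.

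Neuroblastoma cells can take an adrenergic or a mesenchymal state. In the adrenergic list, 2 of 27 genes rose, TBX2 from 113 ± 5.60 to 149 ± 4.72 TPM and GATA3 from 147 ± 6.16 to 187 ± 8.04 TPM (SD, n = 3 each; limma adjusted p = 0.0130 and 0.0211). Both encode transcription factors of this state, and both calls were lost without DMSO replicate 1 or any 1 PTC-028 library (adjusted p up to 0.0772 and 0.0887). Of the 27 genes 3 were higher when adjusted over the list alone. The list was higher by camera (adjusted p = 0.00124), but not with an estimated correlation (adjusted p = 0.124). Among 32 neuronal genes, NEFL, a neurofilament gene, rose from 13.1 ± 0.246 to 20.1 ± 1.35 TPM (limma adjusted p = 0.0160), and VGF was at 0.35 (0.0992). NEFL did not pass without DMSO replicate 1 or PTC-028 replicate 2 or 3 (adjusted p up to 0.0917). Adjusted over the list alone, 12 neuronal genes were higher and 1 was lower. The list had a median of 0.24 and was higher by camera (adjusted p = 0.000302), but not with an estimated correlation (adjusted p = 0.219). In the mesenchymal list, 1 of 14 genes rose, MEF2D (limma adjusted p = 0.0479), which lost the call without any 1 library (adjusted p up to 0.180), under median ratio scaling or quantile normalisation, with a pseudocount of 5 and after GC and length correction. It was the 1 gene higher adjusted over the list alone. VIM was at 0.17 (limma adjusted p = 0.139), and the list did not pass (camera adjusted p = 0.202).

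Several of the largest changes lay outside these lists. ISG20, an exonuclease gene that interferon also induces, had the largest rise by the naming rule, from 1.25 ± 1.002 to 7.50 ± 3.02 TPM (SD, n = 3 each; limma adjusted p = 0.0432), with a wide spread. It lost the call without DMSO replicate 1 or 2 or PTC-028 replicate 1 or 2 (adjusted p up to 0.155), after quantile normalisation and with a pseudocount of 0.1. ANKRD30BL rose by 1.38 (limma adjusted p = 0.0147) and lost the call without DMSO replicate 1 or any 1 PTC-028 library (adjusted p up to 0.0673). The smooth muscle actin gene ACTA2 rose from 6.04 ± 1.25 to 15.7 ± 1.97 TPM and passed in all alternatives. FBXO5, which encodes an inhibitor of the anaphase-promoting complex, fell from 75.9 ± 3.54 to 44.9 ± 1.01 TPM, and DONSON, a replication fork gene, from 29.6 ± 1.26 to 17.4 ± 1.06 TPM, both in all alternatives. NXPH2 fell by 0.77 (limma adjusted p = 0.0295), a call kept without DMSO replicate 3 and lost without any other library (adjusted p up to 0.133). By the naming rule, with its minimum of 5 TPM and the log2(TPM + 1) scale, the largest fall belonged to an alternative-haplotype row of SSBP1, a mitochondrial DNA-binding protein gene, from 99.7 ± 0.934 to 37.0 ± 7.42 TPM, while its primary row was at 173 ± 4.92 and 179 ± 6.93 TPM. The sum of both rows, an alternative chosen after seeing the data, went from 272 ± 5.78 to 216 ± 5.27 TPM, a log2 fold change of -0.33 (limma adjusted p = 0.00912) in place of -1.42 and smaller than that of CCNE2. AC087632.1 on chromosome 15, which overlaps PCLAF and CSNK1G1, fell by 0.70 ± 0.04 (SE; limma adjusted p = 0.000834), and the assignment of reads among the overlapping genes is uncertain.

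Of 52 named genes that passed, 20 passed in all alternatives in which they were tested, with each library left out in turn. SSBP1, 1 of the 20, was not tested with GC and length correction, which needs coordinates. Leaving out DMSO replicate 1, 2 or 3 ended 29, 12 or 7 of the 52 calls, and leaving out PTC-028 replicate 1, 2 or 3 ended 24, 31 or 25. A fit without the filter on low values ended 19 of these calls, and one without the mean-variance trend ended 24. Losses in these 2 fits are not given gene by gene above, so a call may fail in more settings than those named with it.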

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

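The direction of the p53 and replication lists, and of every named gene that passed, held in all alternatives in which they were tested. The log2 fold change of SSBP1 was -1.42 in the row tested and -0.332 in the sum of its rows. The count of genes that passed, 260 (120 higher, 140 lower), was within 1.5 times of this in 8 of 13 alternatives that kept all libraries. It was 138 (59 higher, 79 lower) without a filter, where more genes were tested, and 128 of these were shared with the 260. It was 131 without the mean-variance trend (50 lower), 464 with the GC and length correction chosen after seeing the data (294 lower), and 2219 with library weights (1400 higher, 819 lower). The weights gave DMSO replicate 1 a value of 5.79 and DMSO replicates 2 and 3 values of 0.465 and 0.340, so that fit rests largely on 1 control library. The cause was not tested for the other shifts. Genes changed at least 2-fold numbered 35, against 6 with a pseudocount of 5, which shrinks the folds of low genes, 18 with a minimum TPM of 5 and 107 with library weights. Passing p53 targets numbered 34, against 20 without a filter and 67 with library weights, and passing replication genes 36, against 20 without the trend. With camera at an estimated correlation, 0 of 30 lists passed, against 14 at the preset one and 10 by fry. Those 10 were the p53, replication, repair, histone, immediate-early, adrenergic, neuronal, cholesterol, proteasome and housekeeping lists. The housekeeping list did not pass by camera. With camera at the estimated correlation, the p53 list (median 0.377) and the replication list (-0.495) had an adjusted p of 0.0528, and the tubulin list (-0.108) 0.313. The tubulin list also missed the threshold by fry (-0.108, adjusted p = 0.0615) and after quantile normalisation (-0.0564, adjusted p = 0.0668).

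With 1 library left out, and so fewer samples, 74 to 226 genes passed, 31 to 134 higher and 40 to 127 lower, with 16 to 36 changed at least 2-fold, 16 to 33 p53 targets and 16 to 34 replication genes. The p53 median was then 0.333 to 0.396, the replication median -0.515 to -0.468, the tubulin median -0.125 to -0.0684, and 13 to 16 lists passed at the preset correlation.

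Both groups carry replicate numbers 1 to 3, but these did not pair the samples. Deviations from the group means correlated at 0.0298, -0.0262 and -0.0975 between libraries of the same number, and 1 of the 6 libraries, PTC-028 replicate 1, correlated best with its own number. With the replicate number as a block, 62 genes passed (36 higher, 26 lower), 19 of them at least 2-fold, with 16 p53 targets and 9 replication genes, and 30 of the 52 named calls were lost.

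Results that turned direction had not passed with all libraries, and the cause was not tested. After the turn 1 of them passed, the ribosomal protein list without DMSO replicate 3 (0.0336, adjusted p = 0.00564). For lists, this is the direction of the list test, given with the median. The mitosis list turned after quantile normalisation (0.0310), after GC and length correction (0.0462) and by fry (0.0408), and its median was -0.00368 to 0.0790 with 1 library left out. By fry, the Polycomb complex 1 (0.0141), ribosomal protein (0.00772), hypoxia (0.0457) and interferon (0.0496) lists turned. The HOX list (0.0614) and KIF1B (-0.0237) turned after GC and length correction, and the MYC list (0.0113) after quantile normalisation. Ribosomal proteins also turned with a minimum TPM of 5 (0.00772), after quantile normalisation (-0.00336), without mitochondrial genes (0.0178) and after GC and length correction (-0.0113). Library weights turned the BCL2 list (0.0239) and PTPRC (-0.0823), and the glial list turned without a filter (0.00269). CD68 turned with a pseudocount of 0.1 (-0.00473), median ratio scaling (-0.0163), quantile normalisation (-0.0989) and library weights (-0.0135). With 1 library left out, ranges that include a turn were -0.00168 to 0.0511 (Polycomb complex 1), 0.0262 to 0.101 (HOX), -0.0214 to 0.0336 (ribosomal proteins), -0.0125 to 0.0952 (BCL2), -0.00590 to 0.0534 (hypoxia), -0.0389 to 0.0417 (interferon), -0.113 to 0.0782 (glial), -0.158 to 0.0833 (RNF2) and -0.137 to 0.128 (CD68).

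Read depth cannot be derived from TPM. The median residual SD on the log2 scale was 0.0774 for genes with a mean TPM of 50 or more and 0.219 for those under 5, so small changes of low genes were harder to detect.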

Other observations

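Tests chosen only after the result was seen were those of mitotic cells, of RNA without a poly(A) tail, of a shared fall of tubulin mRNAs, and of other splits of the libraries for the count of genes that passed. The correction for GC content and length used below was also added after seeing the data.

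Energy metabolism and protein turnover lists shifted by small amounts. Nuclear genes of oxidative phosphorylation were lower as a list (median -0.08, 57 of 70 below 0, camera adjusted p = 3.82e-07, adjusted p = 0.400 with an estimated correlation), with 2 members that fell, NDUFB3 and an alternative-haplotype row of NDUFA6, and 2 lower adjusted over the list alone. That list missed the threshold after quantile normalisation (adjusted p = 0.0672) and by fry (0.181). Mitochondrially encoded genes were higher as a list (median 0.19, 12 of 13 above 0, camera adjusted p = 0.00124, adjusted p = 0.513 with an estimated correlation). None of the 13 passed in limma, with 6 at an unadjusted p under 0.05, and MT-ATP8 and MT-CYB were at 0.43 and 0.26. With adjustment over the list alone, 4 were higher, and the list itself missed the threshold with library weights (adjusted p = 0.796) and by fry (0.303). Proteasome subunit genes were lower as a list (median -0.09, 30 of 34 below 0, camera adjusted p = 3.82e-07, adjusted p = 0.0528 with an estimated correlation). None of those 34 passed in limma, with 10 at an unadjusted p under 0.05, and PSMC3 and PSMA3 were at -0.30 and -0.25. Of the 34, 2 were lower when adjusted over the list alone. Cholesterol synthesis genes were lower (median -0.10, camera adjusted p = 0.000122, adjusted p = 0.172 with an estimated correlation), with ACAT2, which makes acetoacetyl-CoA, the 1 of 25 that fell (-0.45 ± 0.06, SE; limma adjusted p = 0.0147) and FDPS at -0.24. Of the 25, 3 were lower when adjusted over the list alone. ACAT2 lost the call without DMSO replicate 1 or PTC-028 replicate 2 or 3 (adjusted p up to 0.0581). The calls for NDUFB3 and NDUFA6 were lost without DMSO replicate 1 or any 1 PTC-028 library, and that for NDUFB3 also without DMSO replicate 2 or 3 (adjusted p up to 0.188 and 0.121). NDUFB3 also lost it under median ratio scaling, quantile normalisation, removal of mitochondrially encoded genes and a pseudocount of 0.1.

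Integrated stress and unfolded protein response genes were lower as a list (median -0.11, camera adjusted p = 0.0101, adjusted p = 0.219 with an estimated correlation), and none of 27 passed in limma, with 11 at an unadjusted p under 0.05. With adjustment over the list alone, 2 were higher and 7 lower, and by fry the list missed the threshold (adjusted p = 0.0615). PHGDH, the entry enzyme of serine synthesis, was at -0.29 and CEBPG at -0.30. The hypoxia and glycolysis list did not pass (camera adjusted p = 0.657), with PGAM1 the 1 of 28 that fell, by 0.22, a call lost without any 1 library (adjusted p up to 0.146) and after quantile normalisation, and TPI1 at -0.20. Of the 28, 1 was higher and 2 were lower when adjusted over the list alone. No member passed in limma in the NF-kB (5 tested, camera adjusted p = 0.236), interferon (14, 0.759), NRF2 (16, 0.659) and lysosome (24, 0.184) lists, with 1, 1, 3 and 4 members at an unadjusted p under 0.05. When each list was adjusted alone, CD83 was lower, GAA was higher and 0 interferon or NRF2 genes passed. The lysosome list was higher by camera without DMSO replicate 3 (adjusted p = 0.0181) and with library weights (0.0152). Their members with the smallest p were CD83 at -0.47, RELB at 0.24, IFI44 at -0.23, MX1 at -0.36, AKR1C2 at 0.46, AKR1C1 at 0.53, GAA at 0.38 and WIPI1 at 0.35. Of 26 housekeeping genes none passed, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.124), and 2 were lower when adjusted over the list alone. The housekeeping list passed by fry (adjusted p = 0.0472). VPS29 was at -0.33 and HPRT1 at -0.25, and the list median of 0.002 and mean of -0.02 differed in sign. The MYC list (camera adjusted p = 0.236) had a median of -0.01 and a mean of 0.002. In the Polycomb complex 1 (camera adjusted p = 0.889), HOX (0.823), ribosomal protein (0.903), hypoxia and interferon lists the median and mean lay above 0 while camera, which compares with all genes, pointed downwards.

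Markers of other cell types gave no call. None of 4 fibroblast genes (camera adjusted p = 0.302) and 4 glial genes (0.733) passed in limma, with 0 at an unadjusted p under 0.05. PDGFRA was at -0.15, THY1 at -0.09 and NGFR at -0.07. Of immune markers 2 were tested, PTPRC at 0.18 and CD68 at 0.001, and no epithelial or endothelial marker reached the filter.

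Among genes in no list, 67 rose and 87 fell. The following were chosen after their values were seen and were not rerun under the alternatives. TOB1, an antiproliferative gene, rose from 40.1 ± 0.873 to 78.7 ± 1.77 TPM, H1F0, a linker histone gene of non-dividing cells, from 81.0 ± 2.06 to 150.4 ± 6.62 TPM, and the histone demethylase gene KDM6B from 36.0 ± 3.07 to 75.5 ± 6.39 TPM (SD, n = 3 each). UNG, which removes uracil from DNA, fell from 184 ± 2.70 to 120 ± 5.39 TPM, and CDK2, a kinase of S phase, from 151 ± 10.3 to 99.5 ± 6.23 TPM.

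Of replication genes 36 of 48 fell, while the mitosis list did not pass, and the lists differed by -0.52 on the log2 scale (camera p = 1.94e-19 against each other, p = 0.00557 with an estimated correlation, and an exact 2-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow). The tables argue against GC content or gene length, since the replication median was -0.495 after each library was corrected for both. A larger share of cells in mitosis is a candidate explanation for the difference. Members that peak in mitosis had a median of 0.16 (17 genes) against -0.03 for the rest (44 genes), a difference of 0.193. The prediction for more mitotic cells asked for at least 0.2, which was just missed, and a camera p under 0.05, which was met at the preset correlation (p = 0.000183). The estimated correlation between genes of the mitosis list was 0.299, against the preset 0.01. This comparison was not run with an estimated correlation, so its p carries little weight. Taken between means instead of medians, the difference was 0.201 (exact 2-sided permutation p = 0.1). The mean log2 value of the replication list was 6.12, 6.18 and 6.10 in DMSO and 5.66, 5.55 and 5.65 in PTC-028. That of the mitosis list overlapped (5.89, 5.96 and 5.84 against 5.84, 5.95 and 5.91). The difference between the lists thus lay mainly in the fall of replication genes, the cause of which was not tested. Whether more mitotic cells added to it cannot be told from these values.

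Of 52 histone genes 8 rose, and the list was higher at the preset correlation but not with an estimated one (adjusted p = 0.0528). Movement of reads among the 63 histone genes of the list, as the only source of the rise, is argued against by their summed TPM. It was higher in PTC-028 by 0.378 on the log2 scale with no overlap between libraries (exact 2-sided permutation p = 0.1, the smallest possible). The sum does not cover copies outside the list, and it does not settle the calls of single members. HIST2H2AA4 and HIST3H2A, named after their values were seen, lay outside it and rose 1.80-fold and 1.67-fold. More RNA without a poly(A) tail in the PTC-028 libraries could raise all histone genes alike. Of the members, 19.23% had a 95% interval wholly below the list median, a share between the bounds set for the test. The 2.5% expected by chance holds only if all members have the same log2 fold change. The scale used understates the change of genes with low TPM, so a shared rise in TPM would also place low members below the median. The share therefore does not measure departure from a shared rise. A fall of S-phase histone RNA in the same libraries would spread the members too, so carry-over and a real rise cannot be told apart.

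Lower tubulin mRNA may reflect a response of the whole family or of single genes. A fall to -0.25 or below shared by all alpha and beta tubulin mRNAs is argued against. Of 8 members with a mean TPM of 50 or more, 6 had 95% intervals wholly above -0.25, while TUBA1B and TUBB lay at -0.31. That bound was set after the values were seen and does not address a smaller shared fall. TUBB2B and TUBB4B had intervals wholly below 0 (-0.24 to -0.01 and -0.22 to -0.0004), whereas those of TUBB2A, TUBA1A, TUBB6 and TUBB3 spanned 0. Whether the fall of TUBA1B and TUBB follows from slower proliferation or from an effect on microtubules was not tested.

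The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 260 genes and the highest of the others 1, so 1 of 10 splits, the real one itself, was as large. For genes changed at least 2-fold the values were 35 and 1, again with only the real split as large. For lists at the preset correlation they were 14 and 10, with only the real split as large. The lowest of the other splits gave 5 lists, although these splits had 0 or 1 genes that passed. List calls at the preset correlation thus also arose under other groupings. Each of the other splits puts 2 libraries of one treatment with 1 of the other and so keeps part of the treatment difference.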
